A study of Mus musculus with 11 samples.

How the data were processed

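RNA from dissected lateral habenula tissue was measured in 11 mouse libraries, in 4 groups of sex and treatment taken from the sample titles and characteristics. The deposited file is a table of whole-number read counts per gene, which the authors made with cutadapt 1.9.1, HISAT2 2.0.5 and featureCounts 1.5.0-p3 on GRCm38, per the submitters' processing notes. The strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The counts were used as deposited, with no normalization by the authors, and all 54532 rows named a gene. Totals were 25317306 to 29565006 counts per library, and counting error covers only reads, not molecules.

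Gene symbols were those of the deposited count table. Coordinates came from GENCODE M21 on GRCm38, to which 54495 of the gene identifiers matched, and the release the authors used may differ. No library pair within a group agreed within sampling noise, with a chi-square per degree of freedom of 7.09 to 30.83 over genes, so each library was counted as 1 replicate.

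Genes were filtered with edgeR's filterByExpr by group, which left 19619. Counts were scaled with TMM factors, and the 4 group means were fitted together in edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, 7 residual degrees of freedom) in R 4.3.3. Fitting all groups together let them share an estimate of the spread, since only 2 male controls exist. The contrasts were CAIA against control over both sexes with equal weight, in females, in males, the difference between these, and female against male. P-values were adjusted by Benjamini-Hochberg over the genes tested, at a threshold of 0.05. Standard errors are the fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes.

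A set of 38 gene lists, covering cell types of the habenula and its neighbours, immune and stress responses, neuronal genes and metabolism, was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of these, 37 had at least 3 tested members and were tested. The lists were tested with camera in limma 3.58.1 on log2 CPM at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. The test was repeated with a correlation estimated per list and with fry. The symbol Ddit3 named more than 1 row of the table, and 1 of these rows had enough counts to be tested. The blood leukocyte markers had too few tested members and were left out.

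The named genes were, for each CAIA comparison, up to 12 genes with the largest rise and 12 with the largest fall among those that passed with a mean of at least 1 CPM. Where fewer than 10 passed, the 10 with the lowest unadjusted p were eligible. From each described list, up to 4 members with the lowest p were added. For the sex difference and for female against male, up to 5 genes in each direction were named, or the 5 lowest p where none passed. Fos, Camk2b, Kcnj10, Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were always included. In males, 3 of the 10 eligible genes are described, and the log2 fold changes of the others were between -1.27 and 0.62.

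The fit was tested on simulated counts for the 19619 genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. In the comparison over both sexes, 76.1% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered. In females these shares were 52.2%, 76.1% and 93.9%, and in males 43.3%, 73.1% and 93.9%. There were 13, 10 and 8 false calls among 186, 158 and 148 calls over both sexes, in females and in males. Only genes with a mean of at least 1 CPM were changed, and counts were drawn independently for each gene and library. Spread that genes share, as through uneven tissue, was not simulated. The shares therefore do not give the power in the real libraries. Alternatives were other size factors, DESeq2 1.42.0, limma-voom with and without quality weights, other count filters, a threshold of 0.1, a surrogate variable from sva 3.50.0, marker levels as covariates, replicate blocks, 1 sex alone, an additive model of sex and treatment, and each library left out in turn. Leaving out a male control leaves a single library in that group, so the spread used in such a fit comes from the other groups alone. Figures were drawn with matplotlib 3.10.9.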

Results

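The study examined the lateral habenula, a small epithalamic nucleus that signals aversive outcomes, in a mouse model of rheumatoid arthritis, with depression as the comorbid condition of interest. Arthritis was induced in 3-month-old BALB/c mice with a cocktail of 5 monoclonal antibodies against type II collagen (50 mg/kg), followed 3 days later by lipopolysaccharide (LPS, 1 mg/kg). This model is called collagen antibody-induced arthritis (CAIA). Control mice received vehicle, so LPS exposure and arthritis cannot be separated here. Total RNA from dissected lateral habenula tissue was sequenced in 11 libraries: 3 female controls, 3 female CAIA, 2 male controls and 3 male CAIA. Total counts ranged from 25317306 to 29565006 per library, and 19619 of the 54532 genes in the table had enough counts to be tested. Each library is labelled as a separate sample, but nothing in the labels says that each came from a different animal, so p-values measure the spread between these samples.

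The first comparison asked which transcripts differed between CAIA and control tissue when both sexes were weighted equally. The main change was a fall of genes expressed by the choroid plexus, the epithelium that secretes cerebrospinal fluid and borders the habenula. The water channel gene Aqp1 fell by 3.89 ± 0.59 (log2 fold change ± SE), an average of the female and male log2 values. In females it was at 18.3 ± 6.39 CPM (counts scaled to library size, mean ± SD, n = 3) in controls and 0.399 ± 0.273 (n = 3) in CAIA, and in males at 17.8 ± 0.86 (n = 2) and 3.68 ± 3.96 (n = 3). The potassium channel subunit gene Kcne2 fell by 3.74 ± 0.52, the carbonic anhydrase gene Car12 by 2.98 ± 0.44, the folate receptor gene Folr1 by 2.50 ± 0.39 and the lysophospholipase D gene Enpp2 by 2.38 ± 0.37. All 14 fixed choroid plexus markers, a list that does not hold Car12, were lower in CAIA, with a median log2 fold change of -2.48. Of these, 7 passed over all genes tested, and 14 passed when adjusted over the list alone. Aqp1 lies on chromosome 6 (55336432 to 55348555, GRCm38) and Kcne2 on chromosome 16 (92292389 to 92298129).

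In total, 117 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 113 of them lower and 4 higher in CAIA. All 113 were lower in each sex by fitted fold change. Over the 19619 genes tested, 199 (1.01%) were lower in every CAIA library than in every control and 33 (0.168%) were higher in every one, where chance gives 0.216% for each direction. Other genes among the largest falls were the protease gene Tmprss11a at -4.12 ± 0.57, a fitted value that rests in part on 2 counts in the female CAIA libraries, the non-coding RNA gene 2900040C04Rik at -3.88 ± 0.69, which rests in part on 3 counts in the same libraries (198 in female controls, a depth-scaled ratio of 70.4 with a 95% counting interval of 23.7 to 344), and the natriuretic peptide clearance receptor gene Npr3 at -2.83 ± 0.39. The cation channel gene Trpv4 fell by 2.67 ± 0.41, the methyltransferase gene Inmt by 2.54 ± 0.33 and the lipid transporter gene Abca4 by 2.34 ± 0.38. The BMP antagonist gene Sostdc1, which is on the fixed choroid plexus list, fell by 2.37 ± 0.35. With the mean level of the choroid plexus markers added to the model, 1 gene passed, and it was not among the 117. This level separates the treatments completely (5.17 to 6.08 in controls and 2.06 to 4.73 in CAIA), so it can stand in for treatment, and a call lost with it does not show that CAIA had no effect. With that level alone Aqp1 was at -0.61 ± 0.46, Kcne2 at -0.61 ± 0.35, Npr3 at -0.13 ± 0.36, Inmt at -0.77 ± 0.82 and Tmprss11a at -0.90 ± 0.84. With it and the medial habenula markers added together, 0 passed. With the choroid plexus level alone, Trpv4, Folr1 and Abca4 turned to 0.052, 0.073 and 0.109, and with both levels 2900040C04Rik turned to 0.656. Leaving out single libraries gave 56 genes without male CAIA replicate 3, 68 without female control replicate 2, and 44, 70 and 43 without female CAIA replicates 1, 2 and 3. The count fell without male control replicate 1 and rose without male control replicate 3, fits that leave a single male control.

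**Figure D1:**
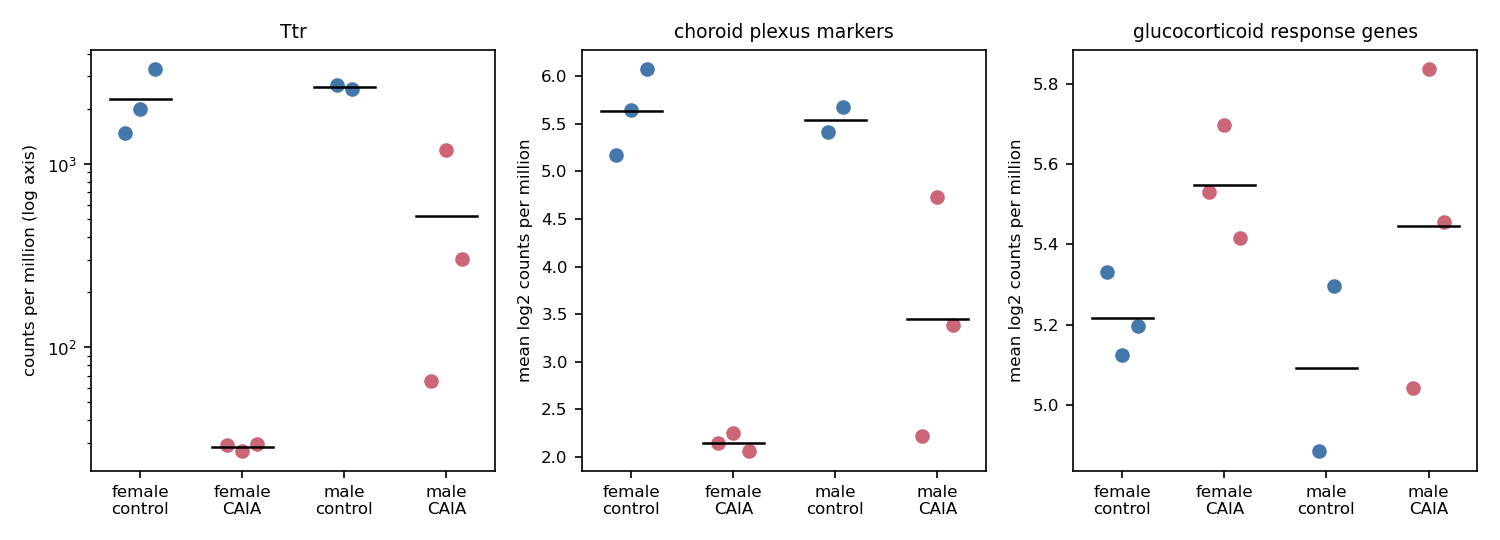
Ttr in CPM on a log axis, and the mean log2 CPM of the choroid plexus markers and of the glucocorticoid response genes, by sex and treatment. Each point is 1 library and each bar a group mean; choroid plexus markers in the female CAIA libraries lay between 2.06 and 2.25, and in the male CAIA libraries between 2.22 and 4.73, all below the 5.17 to 6.08 of the control libraries.

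Transthyretin (Ttr), the main secreted protein of the choroid plexus, was chosen after its values were seen, as the most abundant marker on that list. It stood at 2251 ± 936.5 CPM in female controls (SD, n = 3) and 28.7 ± 1.47 in female CAIA (n = 3). In males it was at 2640 ± 90.2 CPM in controls (n = 2) and 519.5 ± 591.3 in CAIA (n = 3). The 3 male CAIA libraries were uneven, with 1661, 30265 and 8477 Ttr counts.

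The 4 genes that rose were Depp1, Mycl, Mpeg1 and Ptpre. Depp1, a target of FOXO transcription factors, rose by 1.82 ± 0.34 on the log2 scale, from 0.480 ± 0.167 CPM (SD, n = 5) to 1.84 ± 1.03 (n = 6). It lies on chromosome 6 (116650609 to 116652794). The transcription factor gene Mycl rose by 0.57 ± 0.10, the macrophage gene Mpeg1, which encodes perforin-2, by 0.45 ± 0.09, and the phosphatase gene Ptpre by 0.43 ± 0.09. The fitted rise of Ptpre was smaller in females than in males, a difference given below that did not pass. None of the 4 passed with the choroid plexus level in the model, where Depp1 was at 2.66 ± 0.82, Mycl at 0.98 ± 0.22, Mpeg1 at 0.17 ± 0.23 and Ptpre at 0.47 ± 0.22. Cd74, the invariant chain of MHC class II, fell by 1.03 ± 0.18, from 4.75 ± 0.92 CPM (SD, n = 5) to 2.33 ± 0.46 (n = 6). The meningeal fibroblast markers Igf2 and Col1a1 fell by 1.35 ± 0.26 and 0.38 ± 0.08.

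Of the 37 gene lists tested with camera at a preset correlation of 0.01, 9 passed in this comparison. With a correlation estimated for each list, none of the 9 held. The choroid plexus markers fell, with an adjusted p of 5.21e-33, and of 0.216 with an estimated correlation. The glucocorticoid response genes, targets of the corticosterone receptor, rose as a list (adjusted p = 6.52e-08, and 0.408 with an estimated correlation). All 17 had a positive fold change, with a median of 0.35. None of them passed over all genes tested, and 5 passed when adjusted over the list alone. Among them Fkbp5 was at 0.63 ± 0.16, Ddit4 at 0.44 ± 0.10, Tsc22d3 at 0.41 ± 0.12 and Errfi1 at 0.35 ± 0.08. Their mean level was 5.22 ± 0.11 log2 CPM in female controls (SD, n = 3) and 5.55 ± 0.14 in female CAIA (n = 3), with 5.09 ± 0.29 in male controls (n = 2) and 5.45 ± 0.40 in male CAIA (n = 3). Without male CAIA replicate 2, which had the highest level, the median was 0.21. The choroid plexus markers were lower in the same CAIA libraries, by the median of -2.48 given above.

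The MHC class II genes fell as a list (median -0.33, adjusted p = 0.00631, and 0.216 with an estimated correlation), with 6 of 6 members negative and Cd74 passing over all genes and over the list alone. The meningeal fibroblast markers fell (median -0.26, adjusted p = 0.000636, and 0.540 with an estimated correlation), and turned direction, to a median of 0.376, with the choroid plexus level in the model and to 0.286 with the medial habenula level added. With both levels the MHC class II genes turned to 0.148. Of the meningeal fibroblast markers, 2 passed over all genes and 5 when adjusted over the list alone. The type I interferon response genes fell by a median of 0.12 (adjusted p = 0.042, and 0.216 with an estimated correlation). Their median was -0.187 in females and 0.068 in males, where the mean level was 1.208 log2 CPM in controls and 1.184 in CAIA. The astrocyte markers rose by a median of 0.11 (adjusted p = 0.00555, and 0.216 with an estimated correlation), with Gja1 at 0.19 ± 0.07 and Gjb6 at 0.19 ± 0.07. The GABA system genes rose by a median of 0.11 (adjusted p = 0.00555, and 0.218 with an estimated correlation), with Gabra5 at 0.36 ± 0.10, and turned to -0.039 with the choroid plexus level and to -0.020 with both levels. The monoamine and opioid receptor genes rose by a median of 0.10 (adjusted p = 0.00937, and 0.216 with an estimated correlation), with the dopamine receptor gene Drd1 at 0.94 ± 0.21. The hippocampus and cortex markers rose by a median of 0.27 (adjusted p = 0.00878, and 0.540 with an estimated correlation), with C1ql2 at 2.09 ± 0.37. The sexes differed in direction for this list, with a median of -0.157 in females and 0.854 in males. No member of these last 5 lists passed over all genes. Adjusted over the list alone, 2 monoamine and opioid receptor genes and 2 hippocampus and cortex markers passed. The male control libraries had the lowest levels of both the hippocampus and cortex markers and the GABA system genes. The mean GABA system level was 6.96 log2 CPM in female controls and 6.92 in female CAIA, against 6.64 and 7.03 in males. Choroid plexus markers were lower in the CAIA libraries for each of these lists. Male control replicate 1 had the lowest level of monoamine and opioid receptor genes, at 2.89 log2 CPM against 3.20 to 3.51 in the other libraries. Without it this list no longer passed (median 0.05, adjusted p = 0.0994), and the median was 0.18 without male control replicate 3 and 0.15 without female control replicate 3. The hippocampus and cortex markers no longer passed without female control replicate 2 (0.06), female CAIA replicate 1 (0.07) or male control replicate 3 (0.28), and were at 0.64 without female control replicate 1 and 0.165 without male CAIA replicate 2. Removing male control replicate 3 also ended the calls of the astrocyte markers (0.16) and meningeal fibroblast markers (-0.19), and without male CAIA replicate 1 the latter were at -0.17 and the MHC class II genes at -0.20. The MHC class II genes no longer passed without male control replicate 1 (-0.21), nor the GABA system genes without it (0.08) or female control replicate 3 (0.06). The interferon list no longer passed without any one of male control replicates 1 and 3, male CAIA replicates 2 and 3, female control replicates 2 and 3 and female CAIA replicate 1 (medians -0.116 to -0.054).

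Because the study concerns habenular activity, 3 genes were fixed for description in every comparison. The dissected tissue also held RNA of its neighbours. Group means were 6.56 to 6.71 log2 CPM for medial habenula markers, 7.15 to 7.52 for thalamus markers and 7.08 to 7.20 for lateral habenula markers. Such levels do not measure amounts of tissue. The values below are those of the dissected tissue and not of the lateral habenula alone. The activity-induced gene Fos was at 0.30 ± 0.22 (log2 fold change ± SE, both sexes), the calcium/calmodulin kinase gene Camk2b at 0.12 ± 0.08 and the astrocytic potassium channel gene Kcnj10 at 0.12 ± 0.07, and none passed (edgeR adjusted p = 0.92, 0.882 and 0.881). Kcnj10 turned to -0.095 with the choroid plexus level in the model. Fos counts were 30.6 ± 7.32 CPM in controls (SD, n = 5) and 36.1 ± 9.59 in CAIA (n = 6). The lateral habenula markers had a median of 0.05 (camera adjusted p = 0.40), the genes studied in the lateral habenula in depression models 0.05 (adjusted p = 0.0836), and the immediate early genes -0.07 (adjusted p = 0.703, with a test direction opposite in sign to the median). The cytokine and NF-kB genes had a median of -0.01 (adjusted p = 0.844) and the homeostatic microglia markers 0.07 (adjusted p = 0.0652). Of the cytokine list, Il1b, Il6, Tnf, Il1rn, Ccl2, Ccl5, Cxcl1, Cxcl2 and Il10 had too few counts to be tested. Its median therefore says nothing on these genes.

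**Figure D2:**
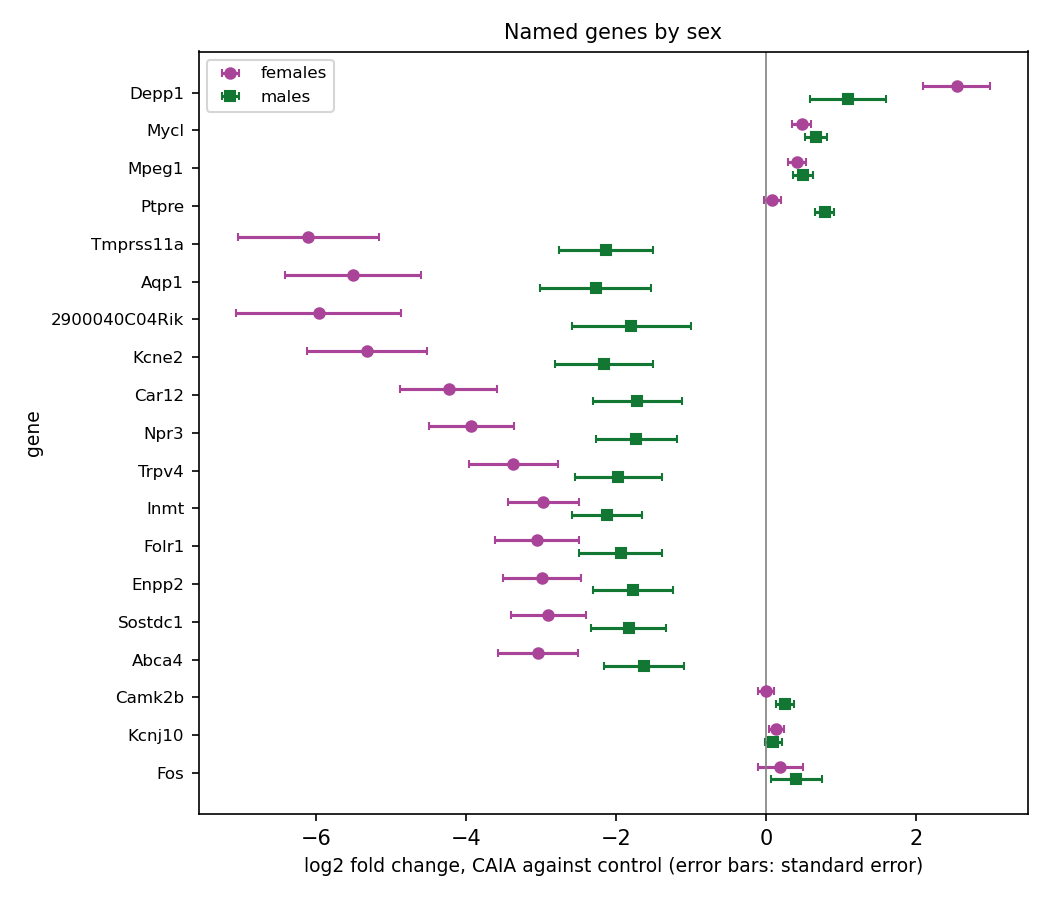
Log2 fold change of CAIA against control, in females and in males, for the named genes of the comparison over both sexes and for Camk2b, Kcnj10 and Fos. Points are fitted values from 3 CAIA and 3 control libraries in females and from 3 CAIA and 2 control libraries in males, and bars are standard errors; the female values of Tmprss11a and 2900040C04Rik rest on 2 and 3 counts in CAIA. Depp1, for example, was at 2.54 ± 0.44 in females and Aqp1 at -5.51 ± 0.91.

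In females alone, 51 genes passed, 50 lower and 1 higher in CAIA, and 50 of the 51 also passed in the comparison over both sexes. Depp1 rose by 2.54 ± 0.44 on the log2 scale. Npr3 fell by 3.93 ± 0.57, Inmt by 2.97 ± 0.47, the fibroblast protease gene Fap by 2.87 ± 0.45 and the RNA-binding protein gene Rbm47 by 2.61 ± 0.44. The prolactin receptor gene Prlr fell by 2.20 ± 0.30, Wdr86 by 2.13 ± 0.34, the growth factor gene Igf2 by 1.98 ± 0.36 and Frem1 by 1.93 ± 0.28. Pon3 fell by 1.92 ± 0.25, Large2 by 1.87 ± 0.34 and the collagen-processing gene Pcolce by 1.83 ± 0.26. Tmprss11a also fell, with 155 counts in the 3 female control libraries and 2 in the 3 female CAIA libraries, a depth-scaled ratio of 82.6 with a 95% counting interval of 22.5 to 689. All 14 choroid plexus markers were negative, with a median of -3.06 (adjusted p = 1.2e-32, and 0.127 with an estimated correlation). Of these Prlr alone passed over all genes, while 14 passed when adjusted over the list alone.

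In females 11 lists passed, and none held with an estimated correlation. The glucocorticoid response genes rose by a median of 0.33 (adjusted p = 2.52e-06, and 0.423 with an estimated correlation). In this list Errfi1 was at 0.49 ± 0.11 and Nfkbia at 0.56 ± 0.16, and 4 members passed when adjusted over the list alone and none over all genes. The type I interferon response genes fell by a median of 0.19 (adjusted p = 0.000679, and 0.127 with an estimated correlation), and the meningeal fibroblast markers by 0.48 (adjusted p = 1.28e-07, and 0.328 with an estimated correlation). The MHC class II genes fell by a median of 0.33 (adjusted p = 0.0124, and 0.235 with an estimated correlation). The medial habenula markers rose by a median of 0.13 (adjusted p = 0.018, and 0.775 with an estimated correlation), with Zic1 at 0.17 ± 0.10 and Tac1, the substance P precursor gene, at 0.28 ± 0.18. The astrocyte markers rose by 0.10 (adjusted p = 0.0173, and 0.235 with an estimated correlation), the heat shock genes by 0.10 (adjusted p = 0.0281, and 0.423 with an estimated correlation) and the endoplasmic reticulum stress genes by 0.09 (adjusted p = 0.018, and 0.423 with an estimated correlation). Choroid plexus markers were lower in the same libraries for each of these lists. With the choroid plexus level in the model, the meningeal fibroblast markers turned to a median of 0.387, the endoplasmic reticulum stress genes to -0.069, Rbm47 to 0.214, Wdr86 to 0.001 and Large2 to 0.134, and with both levels the MHC class II genes turned to 0.358 and the heat shock genes to -0.006. The count of 51 genes was 0 without any one of the 3 female CAIA libraries, 1 without female control replicate 3, 29 without female control replicate 2, 24 without male CAIA replicate 3, and 103 and 104 without male CAIA replicates 1 and 2. With the choroid plexus markers' level in the model, which separates the female groups completely, it was 0, and with the pineal markers' level 3. The medial habenula markers no longer passed without female control replicate 1 (median 0.065) or 2 (0.04) or female CAIA replicate 3 (0.04), and were at 0.30 without female control replicate 3. The heat shock genes no longer passed without female control replicate 2 (0.09) or 3 (0.11) or female CAIA replicate 1 (0.13) or 3 (0.07), the astrocyte markers without female control replicate 2 (0.09) or female CAIA replicate 2 (0.08), the endoplasmic reticulum stress genes without female control replicate 2 (0.05) and the MHC class II genes without female CAIA replicate 2 (-0.54). The interferon list was at -0.12 without female CAIA replicate 1.

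In males no gene passed in edgeR's quasi-likelihood test (smallest adjusted p = 0.167), while DESeq2 called 71. In edgeR 1104 genes had an unadjusted p under 0.05, where chance gives 981. The lowest p belonged to Col9a3, a collagen gene at -0.94 ± 0.15, followed by the pro-apoptotic gene Hrk at 0.95 ± 0.15 and Ptpre at 0.78 ± 0.13, none of which passed. The choroid plexus markers fell as a list by a median of 1.83 (adjusted p = 2.58e-17, and 0.264 with an estimated correlation). No member passed over all genes and 10 passed when adjusted over the list alone. Without male CAIA replicate 2 the median was -2.775. Without male CAIA replicate 2, 36 genes passed. The count also rose without male control replicate 3, where a single male control is left and its group has no spread of its own.

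Of the other lists, the hippocampus and cortex markers rose (median 0.85, adjusted p = 6.62e-06, and 0.264 with an estimated correlation), with C1ql2 at 2.73 ± 0.59. The glucocorticoid response genes rose by a median of 0.24 (adjusted p = 0.000591, and 0.704 with an estimated correlation), and 1 member, Fkbp5 at 0.94 ± 0.24, passed when adjusted over the list alone. Male control replicate 1 had the lowest level of this list of all 11 libraries, at 4.88 log2 CPM, and male CAIA replicate 1, at 5.04, lay below male control replicate 3, at 5.30. The list no longer passed without male control replicate 1 (median 0.11, adjusted p = 0.32) or male CAIA replicate 2 (0.12, adjusted p = 0.163), and was at 0.43 without male control replicate 3 and 0.405 without male CAIA replicate 1. The endothelial response to systemic LPS rose by a median of 0.33 (adjusted p = 0.0261, and 0.458 with an estimated correlation), with the transcription factor gene Cebpd at 1.07 ± 0.24 and the interleukin-1 receptor gene Il1r1 at 0.88 ± 0.22. For this list 4 members passed when adjusted over the list alone and none over all genes. Male CAIA replicate 2 stood apart at 2.74 log2 CPM, while male CAIA replicate 3, at 1.97, lay below male control replicate 1, at 2.04, and male control replicate 3 was lowest, at 1.62. The list no longer passed without male CAIA replicate 2 (median 0.005, adjusted p = 0.16) or male control replicate 3 (0.04, adjusted p = 0.237), and was at 0.60 without male CAIA replicate 3. The immediate early genes rose by 0.27 (adjusted p = 0.0435, and 0.771 with an estimated correlation) and the genes studied in the lateral habenula in depression models by 0.23 (adjusted p = 0.0435, and 0.647 with an estimated correlation), with the glutamate receptor gene Gria2 at 0.45 ± 0.16. The GABA system genes rose by 0.15 (adjusted p = 0.00164, and 0.264 with an estimated correlation) and the voltage-gated and pacemaker channel genes by 0.13 (adjusted p = 0.00892, and 0.771 with an estimated correlation), while the endoplasmic reticulum stress genes fell by 0.20 (adjusted p = 0.000128, and 0.264 with an estimated correlation). Choroid plexus markers were lower in the same libraries for each of these lists. The 2 male controls also had the lowest mean levels of hippocampus and cortex markers, tissue that neighbours the habenula, at 1.86 and 2.01 log2 CPM against 2.29 to 3.99 in the other libraries, and of GABA system genes, at 6.58 and 6.70 against 6.79 to 7.15. Male control replicate 1 had the lowest level of all 11 libraries for the channel genes (6.59), the genes studied in depression models (7.12) and the immediate early genes (3.76) as well. With both levels in the model the genes studied in depression models had a median of -0.038. Without male control replicate 1 the channel genes' median was -0.03, and the list no longer passed without male CAIA replicate 1 (0.09) or 2 (0.08) and was at 0.33 without male control replicate 3. The GABA system genes no longer passed without male control replicate 1 (0.11), and the hippocampus and cortex markers were at 1.74 without male control replicate 3. The immediate early genes and the genes studied in depression models no longer passed without either male control (0.067 and 0.378, and 0.065 and 0.21, for replicates 1 and 3), male CAIA replicate 2 (0.143 and 0.184) or female CAIA replicate 3 (0.266 and 0.23), nor the former without male CAIA replicate 3 (0.186) and the latter without male CAIA replicate 1 (0.154) or female control replicate 2 or 3 (0.23 for each).

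The sex difference of the CAIA effect was tested as an interaction. No gene passed in edgeR (smallest adjusted p = 0.978), 807 genes had an unadjusted p under 0.05, fewer than the 981 that chance gives, and DESeq2 called 2. The 5 genes with the lowest p were Hrk, Ak5, Ptpre, Sh3bp5 and Skil, with differences, females minus males, of -0.97 ± 0.20, -1.19 ± 0.27, -0.70 ± 0.17, -0.70 ± 0.17 and -0.62 ± 0.15. For 12 lists the difference passed camera at the preset correlation, and none of them held with an estimated one. The nuclear-encoded respiratory chain genes had a median of 0.09 in females and -0.14 in males (adjusted p of the difference 2.51e-10, and 0.747 with an estimated correlation). The ribosomal protein genes had 0.11 and -0.12 (adjusted p = 5.61e-08, and 0.747 with an estimated correlation). These lists also passed within each sex, with adjusted p of 7.74e-05 and 8.77e-05 in females (0.775 for both with an estimated correlation) and 3.8e-05 and 0.00195 in males (0.771 and 0.821 with an estimated correlation). Male control replicate 1 had the highest level of both lists, at 6.37 log2 CPM each, against at most 6.21 and 6.16 in the other libraries. Without it the male medians were 0.05 and 0.11 and the difference no longer passed (0.04 and -0.03, adjusted p = 0.146 and 0.973). Without male control replicate 3 the differences were 0.43 and 0.40 and the male medians -0.31 and -0.30, and without male CAIA replicate 2 neither list passed in males (-0.095 and -0.069). Without male CAIA replicate 3 the male ribosomal protein median was -0.175. In females the respiratory chain genes no longer passed without female control replicate 3 (0.04) or female CAIA replicate 3 (0.01), and were at 0.17 and 0.15 without female control replicate 1 and female CAIA replicate 1, and the ribosomal protein genes were at 0.06 without female CAIA replicate 3. With the choroid plexus level in the model the female medians were -0.200 and -0.123.

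**Figure D3:**
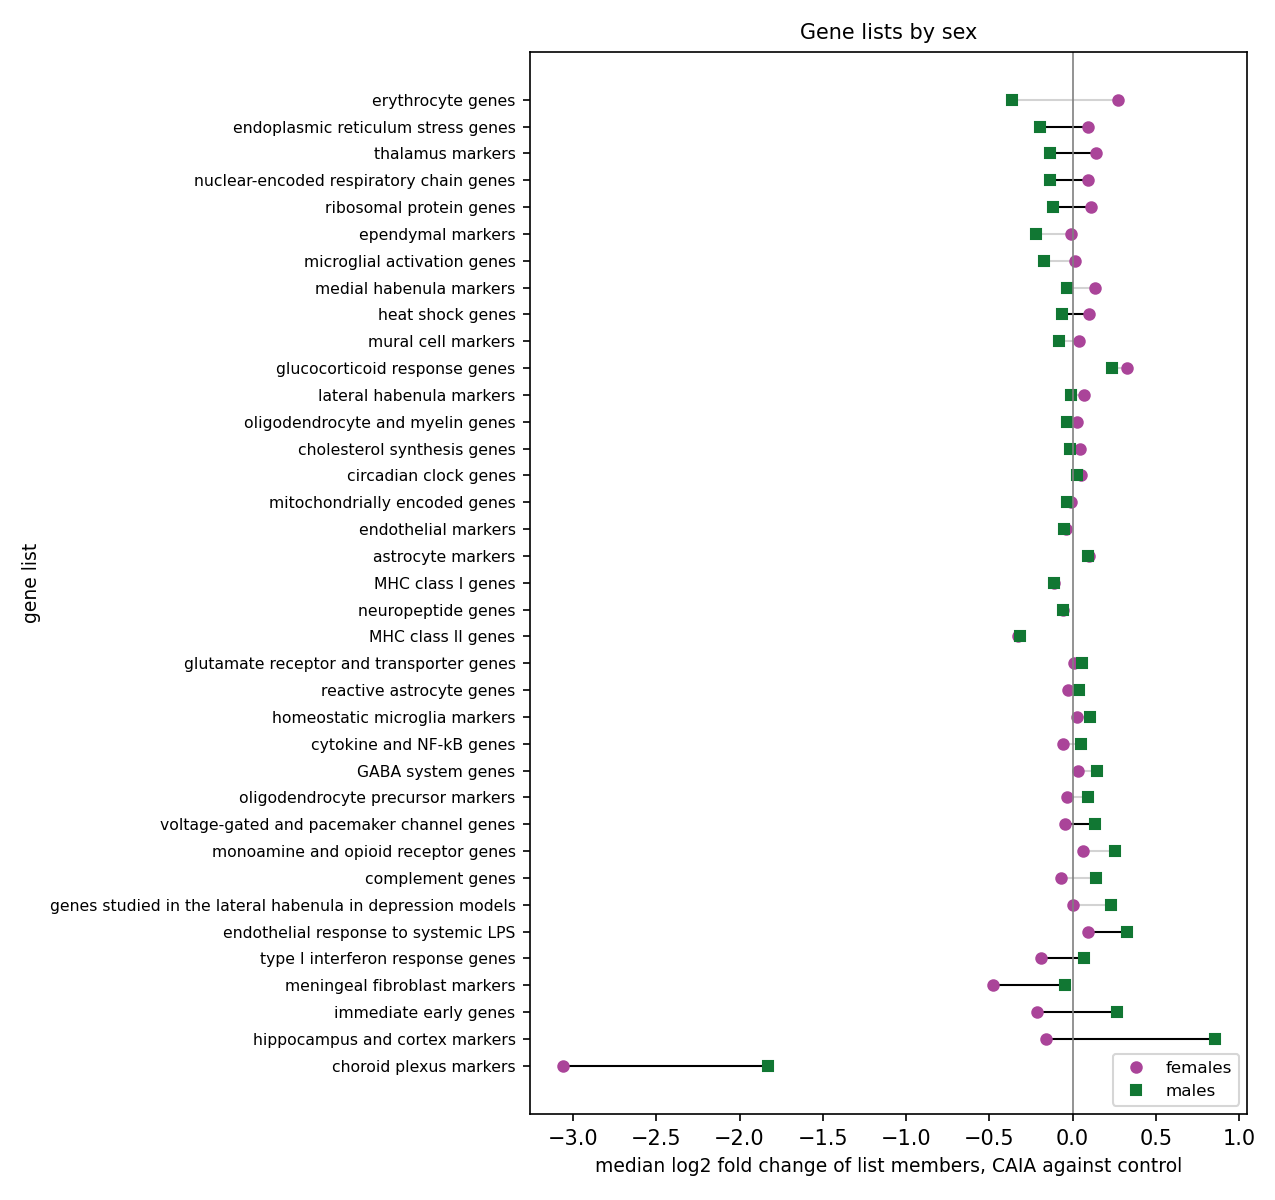
Median log2 fold change of CAIA against control over the members of each of the 37 lists tested, in females and in males. A black line joins the 2 sexes where the difference passed at the preset correlation (12 lists) and a grey line where it did not; choroid plexus markers were at -3.06 in females and -1.83 in males.

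Across genes, the log2 fold changes of females and males correlated weakly, with a Pearson r of 0.159 and a Spearman rho of 0.056 over the 19619 genes, which are not independent replicates. The same sign was found for 51.2% of all genes tested, and for 60.3% of the 1913 genes with an unadjusted p under 0.05 in either sex. The sexes shared no control library. Leaving out single libraries gave a Pearson r of 0.008 to 0.301: 0.008 without male control replicate 3, 0.105, 0.301 and 0.05 without male CAIA replicates 1, 2 and 3, and 0.094 without female control replicate 2.

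Female and male tissue was compared to check the sex labels and to measure the difference between the sexes. Xist, the non-coding RNA of the inactive X chromosome, was higher in females, and the Y-linked genes Ddx3y, Eif2s3y, Uty, Kdm5d and Gm29650 were lower. The X-linked genes Eif2s3x, Ddx3x and 5530601H04Rik were higher in females, with log2 fold changes of 0.67 ± 0.05, 0.48 ± 0.06 and 0.55 ± 0.08. These 9 genes were all that passed, 4 higher and 5 lower in females. Xist had 14933 to 22396 counts in the female libraries and 3 to 46 in the male libraries. The counts of Ddx3y, Eif2s3y, Uty and Kdm5d together were 3567 to 4944 in the male libraries and 0 to 11 in the female libraries. More genes passed without male control replicate 3, a fit that leaves a single male control.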

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

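Of the tests in this part, the one on time of day and the count of splits in either direction for the glucocorticoid response genes were chosen after the result was seen. For 12 gene lists the CAIA effect differed between females and males in a camera test of the difference, with none holding at an estimated correlation (lowest adjusted p = 0.196, for the endoplasmic reticulum stress genes). The median differences, females minus males, were -1.276 for hippocampus and cortex markers, -1.207 for choroid plexus markers, -0.581 for meningeal fibroblast markers, -0.302 for immediate early genes, -0.281 for type I interferon response genes, -0.268 for the endothelial response to systemic LPS and -0.167 for voltage-gated and pacemaker channel genes. They were 0.274 for thalamus markers, 0.271 for endoplasmic reticulum stress genes, 0.251 for nuclear-encoded respiratory chain genes, 0.208 for ribosomal protein genes and 0.168 for heat shock genes. The hippocampus and cortex markers, the choroid plexus markers and the endoplasmic reticulum stress genes passed without each library in turn, although the choroid plexus difference was -0.667 without male CAIA replicate 2. The other 9 lists each no longer passed without at least 1 library.

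The thalamus difference of 0.274 was -0.014 without female control replicate 3, so this library alone removes it. It also no longer passed without male control replicate 1 (0.228) or 3 (0.315) or male CAIA replicate 3 (0.159), and was 0.139 without female CAIA replicate 3 and 0.628 without female control replicate 2. The channel gene difference of -0.167 was -0.011, with the test's direction turned, without male control replicate 1. It also no longer passed without male CAIA replicate 1 (-0.107) or 2 (-0.138), female control replicate 1 (-0.096) or 2 (-0.118) or female CAIA replicate 2 (-0.179) or 3 (-0.136), and was -0.370 without male control replicate 3. The respiratory chain and ribosomal protein differences were 0.040 and -0.026 without male control replicate 1, no longer passing, and 0.427 and 0.404 without male control replicate 3.

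The meningeal fibroblast difference of -0.581 was -0.215 without male CAIA replicate 2 and -0.354 without female control replicate 3, and no longer passed without male control replicate 1 (-0.454). The immediate early gene difference of -0.302 no longer passed without female control replicate 1 (-0.117), male CAIA replicate 3 (-0.217), female CAIA replicate 2 (-0.256) or male control replicate 1 (-0.303). The interferon difference of -0.281 no longer passed without female control replicate 2 (-0.173) or 3 (-0.222), male control replicate 1 (-0.186) or 3 (-0.235) or female CAIA replicate 1 (-0.299), and was -0.183 without male CAIA replicate 2 and -0.184 without female CAIA replicate 3. The endothelial LPS difference of -0.268 no longer passed without male CAIA replicate 2 (-0.173) or male control replicate 3 (-0.427), and was -0.632 without male CAIA replicate 3, -0.598 without male control replicate 1, -0.466 and -0.488 without female control replicates 2 and 3 and -0.538 without female CAIA replicate 1. The heat shock difference of 0.168 no longer passed without male control replicate 3 (0.124), and was 0.107 without female control replicate 2.

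The respiratory chain and ribosomal protein genes moved apart in the sexes, by a median of 0.233 over 121 genes. In males their median was -0.130; without male control replicate 1 it was 0.086, and without male control replicate 3 it was -0.304, so 1 male control library may set this difference. A set of 453 other genes matched on exon length and mean CPM differed by 0.141, which is 0.606 of the lists' difference, so a bias by gene length between libraries also stays open. A difference between the sexes is not excluded.

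The genes that were lower in CAIA over both sexes had a technical candidate in uneven amounts of choroid plexus in the dissected tissue. Of the 113, 106 were not on the choroid plexus list, and their median within-group correlation with the choroid plexus level was 0.755, against 0.014 over all genes tested. Most of that level's within-group spread came from male CAIA replicates 1 and 2 (2.22 and 4.73), so the correlation rests largely on them. Among 100 splits of the libraries within sex, drawn from 200 possible, 2 called as many genes as the real split, itself included. This share is under 0.05, but it does not exclude chance, since another split called more genes. The real split called 117 genes and the highest other 154. That other split set the 5 controls and male CAIA replicate 2, the CAIA library with the highest choroid plexus level, against the rest. It points to a structure of the samples along that level. No marker on this list is on another list, although oligodendrocytes also make Enpp2, and Ttr, the most abundant marker, stood at 2407 CPM in controls and 274.1 in CAIA. Whether the tissue differed by dissection or by an effect of CAIA or LPS on the choroid plexus stays open, since both follow the groups.

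For the rise of the glucocorticoid response genes, uneven choroid plexus predicts a negative correlation with the choroid plexus level within groups. Within groups their median correlation with it was 0.611, positive, whereas CAIA libraries had lower choroid plexus marker levels and, on average, higher levels of these genes. Most of the within-group spread of that level came from male CAIA replicates 1 and 2, at 2.22 and 4.73 (2.06 to 2.25 in the female CAIA libraries). Male CAIA replicate 2 also had the highest level of these genes. The correlation thus rests largely on these libraries and cannot settle whether uneven choroid plexus played a part. For a different time of day, 6 rhythmic genes were examined: Dbp, Nr1d1, Ciart, Per2, Per3 and Arntl. They had a median absolute log2 fold change of 0.087 with an upper bootstrap limit of 0.178, below the list's 0.352. The bootstrap drew over genes, so it leaves out the spread between libraries. Dbp was at -0.148 ± 0.074 and Nr1d1 at -0.208 ± 0.104, and the others at 0.004 to 0.098. A shift as large as the list's rise was thus not seen in these genes, while a smaller one stays open. Of 100 splits within sex, 2 gave a rise with a p as small, itself included, but the test is two-sided and 5 gave a change as strong in either direction, so chance is not excluded, with 3.52e-09 for the real split and 3.57e-19 for the lowest other. The list's adjusted p was 0.408 with an estimated correlation. A response to arthritis or to LPS remains an untested hypothesis.

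For the 9 genes that passed between females and males, 3 of 100 splits within treatment called as many, itself included, with 32 genes in the highest other split. This share is under 0.05 but does not exclude chance for the count. All 9 genes are X-linked or Y-linked, so the count says little beyond the sex labels. In females the real split called 51 genes and the highest of the other splits 0, but the 10 splits are too few for a share under 0.05, the real one being the 1 split as large.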

How the results depend on the processing

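Alternatives with the choroid plexus level alone, with the pineal level and with genes that follow the choroid plexus level left out were chosen after seeing the data. Except where said, the cause of a change was not tested. The choroid plexus level is higher in every control library than in every CAIA library, so a model that holds it can take up an effect of CAIA, and a lost call or a turned direction under it is no evidence that CAIA had no effect. Over all alternatives, the values of single named genes kept direction and side of the threshold 1076 times, lost their call 302 times, gained one 40 times and turned direction 29 times, and those of lists did so 425, 193, 0 and 27 times.

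CAIA against control over both sexes called 117 genes. The count was 179 at an adjusted p of 0.1, 222 with DESeq2 and 470 with no filter on low counts. It was 25 with genes following the choroid plexus level left out, 1 with the choroid plexus level and 0 with the medial habenula and choroid plexus levels in the model. The genes left out had a within-group correlation with that level of 0.5 or more. Because this correlation rests largely on male CAIA replicates 1 and 2, the 25 genes are not shown to be free of choroid plexus. Leaving out each library gave 43 to 180. In females the count of 51 became 91, 171, 452, 5, 0 and 0 under the same alternatives, 100 with quality weights, 3 with the pineal level, 108 in the female libraries alone and 82 with a replicate block within sex. Leaving out each library gave 0 to 104 in females and 0 to 142 in males. In males the count of 0 became 71 with DESeq2, 423 with no filter, 1 with either set of levels, 43 in the male libraries alone, and 1 and 31 with a replicate block and with a replicate block within sex. The sex difference gave 2 genes with DESeq2 and 316 with no filter. Female against male gave 23 with DESeq2 and 278 with no filter. The correlation of female and male effects moved to 0.645 with both levels, where both effects are adjusted by the same fitted slopes and so share error by construction, and was 0.008 to 0.301 leaving out each library.

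Same-numbered libraries did not deviate together (0.12, -0.09 and -0.164 in females, -0.016 and -0.287 in males), and different-numbered ones had -0.286 to 0.287. This gave no sign that the numbers pair the samples. With 2 or 3 libraries per group, deviations from the group mean depend on each other. A shared litter, batch or day is therefore not excluded. The replicate block called 115 genes over both sexes, 45 in females, 0 for the sex difference and 8 for female against male. Within sex it called 126 over both sexes.

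Of the lists, 0 passed in any CAIA comparison with an estimated correlation. With fry 1 passed over both sexes, 2 in females, 0 in males and 0 for the sex difference. With both levels in the model 2 passed in females and 6 for the sex difference, and with the choroid plexus level alone 6 in females. Leaving out each library gave 6 to 13 lists in males and 7 to 17 for the sex difference.

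Reversed medians with both levels and with the choroid plexus level alone were, over both sexes, 0.286 and 0.376 for meningeal fibroblast markers and -0.020 and -0.039 for GABA system genes. In females they were 0.346 and 0.387 for meningeal fibroblast markers, -0.092 and -0.200 for respiratory chain genes, 0.010 and -0.123 for ribosomal protein genes and -0.216 and -0.069 for endoplasmic reticulum stress genes. In males they were -0.038 and 0.007 for genes studied in the lateral habenula in depression models. With both levels, MHC class II genes turned to 0.148 over both sexes and 0.358 in females, and heat shock genes to -0.006 in females. A list's direction is set by its test, so some medians keep their sign. Where a list is its own covariate the model removes it by construction: choroid plexus markers were at -0.056 with their level alone over both sexes, at -0.058 and -0.011 in females and at 0.117 and 0.254 for the sex difference, and medial habenula markers at -0.015 in females. Leaving out each library gave -0.031 to 0.334 for voltage-gated channel genes, -0.313 to 0.049 for respiratory chain genes and -0.299 to 0.111 for ribosomal protein genes in males, and -0.370 to -0.011 for voltage-gated channel genes in the sex difference. Male control replicate 1 was the library whose removal turned these.

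Among genes over both sexes, both levels and the choroid plexus level alone turned Trpv4 to 0.221 and 0.052, Folr1 to 0.120 and 0.073, Abca4 to 0.193 and 0.109 and Kcnj10 to -0.066 and -0.095, and both levels turned 2900040C04Rik to 0.656. In females Large2 turned to 0.450 and 0.134 and Kcnj10 to -0.084 and -0.126, and the choroid plexus level alone turned Rbm47 to 0.214 and Wdr86 to 0.001. In males Kcnj10 turned to -0.049 and -0.064, and ranged from -0.004 to 0.210 leaving out each library. Camk2b in females, at 0.000 and far from passing, was at -0.001 with other size factors, -0.001 with DESeq2, -0.030 with quality weights, -0.007 with the stricter filter, -0.011 with a surrogate variable, -0.068 with the choroid plexus level, and -0.084 to 0.070 leaving out each library.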

Other observations

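The other gene lists had small medians in the comparison over both sexes. These were 0.05 for medial habenula markers, -0.01 for thalamus markers, -0.05 for ependymal markers, -0.02 for reactive astrocyte genes, -0.07 for microglial activation genes, -0.01 for oligodendrocyte and myelin genes, 0.02 for oligodendrocyte precursor markers, -0.05 for endothelial markers and -0.03 for mural cell markers. They were -0.01 for erythrocyte genes, 0.22 for the endothelial response to systemic LPS, -0.09 for MHC class I genes, 0.02 for complement genes, 0.03 for glutamate receptor and transporter genes, 0.04 for voltage-gated and pacemaker channel genes and -0.04 for neuropeptide genes. They were -0.03 for respiratory chain, mitochondrially encoded and endoplasmic reticulum stress genes, -0.01 for ribosomal protein genes, 0.01 for cholesterol synthesis genes, 0.03 for heat shock genes and 0.06 for circadian clock genes. None of these passed camera. Of the microglial activation genes, Cst7, Clec7a, Ccl3, Ccl4, Il1b, Tnf and Ccl2 had too few counts to be tested. For thalamus, reactive astrocyte, neuropeptide, erythrocyte and ribosomal protein genes the test's direction was up although the median was negative, and for complement genes it was down although the median was positive. The endothelial genes Slco1c1 and Kdr fell by 0.50 ± 0.07 and 0.49 ± 0.10, and the reactive astrocyte gene Steap4 by 1.67 ± 0.34, and these were chosen after their values were seen. In the endothelial LPS list, Cebpd was at 0.74 ± 0.16 and Il1r1 at 0.49 ± 0.15. Neither passed over all genes, and 4 members passed when adjusted over the list alone.

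In the comparison of females with males, 14 lists passed camera and none held with an estimated correlation. The respiratory chain and ribosomal protein genes were lower in females, with medians of -0.13 and -0.12 (adjusted p = 1.94e-06 for each, and 0.558 with an estimated correlation). Male control replicate 1 had the highest level of both lists, at 6.37 log2 CPM each, against at most 6.21 and 6.16 in the other libraries. Without it the medians were -0.025 and -0.009 and neither list passed (adjusted p = 0.483 and 0.852), so the fall in females rests on this library. Without male control replicate 3 they were -0.217 and -0.214. The choroid plexus markers, at -0.62 (adjusted p = 0.00692, and 0.558 with an estimated correlation), and the thalamus markers, at -0.15 (adjusted p = 0.0419, and 0.587 with an estimated correlation), were lower in the same comparison. For choroid plexus this lay in the CAIA libraries, at 2.151 log2 CPM in females and 3.448 in males. Female controls, at 5.631, were not below male controls, at 5.546. For thalamus it lay mostly in the controls, at 7.146 in females and 7.523 in males, against 7.325 and 7.349 in CAIA. The ependymal markers were higher in females by a median of 0.30 (adjusted p = 0.000933, and 0.558 with an estimated correlation). The heat shock genes were higher in females by a median of 0.13 (adjusted p = 2.02e-05, and 0.501 with an estimated correlation) and the immediate early genes by 0.20 (adjusted p = 0.00147, and 0.558 with an estimated correlation). Mean heat shock levels were 6.359 log2 CPM in female and 6.278 in male controls, and 6.462 and 6.142 in CAIA. Those of the immediate early genes were 4.345 and 3.874 in controls, and 4.104 and 4.134 in CAIA. The rest, reactive astrocyte, oligodendrocyte precursor, glucocorticoid response, astrocyte, cytokine, homeostatic microglia and GABA system genes, were higher in females by medians of 0.05 to 0.12 (adjusted p = 0.0198 to 0.0478, and 0.558 to 0.587 with an estimated correlation). Of the 14, only the heat shock genes passed without each library in turn. The choroid plexus markers no longer passed without male control replicate 3 (-0.596), male CAIA replicate 2 (-0.194) or female control replicate 1 (-0.529), the ependymal markers without male control replicate 3 (0.239) and the immediate early genes without female control replicate 1 (0.057). The ependymal markers were at 0.177 without female control replicate 3. The thalamus markers no longer passed without male control replicate 1 or 3 (-0.156 and -0.138), male CAIA replicate 1 (-0.088), female control replicate 1 or 3 (-0.126 and -0.028) or female CAIA replicate 2 (-0.121), and were at -0.298 without female control replicate 2. The 7 lists with small medians each failed to pass without at least 2 of the libraries, with medians of 0.031 to 0.253 over all libraries left out.

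Pineal markers, chosen after the data were seen, differed between libraries within groups. Tph1 was at 19.2 CPM in male CAIA replicate 3 and 15.9 in female CAIA replicate 2, at 2.77 to 4.39 in male control replicate 1, female control replicate 3 and female CAIA replicate 1, and at most 0.378 in the other libraries. Rbp3 reached 20.3 and 21.1 CPM in the first pair. Sag and Crx were also highest in that pair. Aanat did not follow, at 1.15 and 0.628 CPM there and 0.569 to 1.47 over all libraries.

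A few reads of the other sex's genes were found in 2 libraries. Male CAIA replicate 3 had 46 Xist counts, against 3 to 5 in the other males, and female CAIA replicate 3 had 11 counts of the Y-linked genes, against 0 in the other females.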
